A study of Arabidopsis thaliana with 4 samples.

How the data were processed

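RNA from cotyledons of Arabidopsis thaliana was compared on 4 two-colour Agilent oligonucleotide arrays. On each array, plants overexpressing CUC1 from the 35S promoter were hybridised directly against their own control, so the sample of each array is a ratio of 35S:CUC1 over control. A pair of arrays compared 35S:CUC1 with wild-type Ler at day 5, and another pair compared 35S:CUC1 stm with stm at day 10. Per the series' design text, each comparison had 2 independent biological replicates. The dyes were swapped within each pair: 35S:CUC1 carried Cy5 on Ler replicate 1 and stm replicate 2, and Cy3 on Ler replicate 2 and stm replicate 1. The dyes in the table's headers matched those in the labels. The genetic background and the age of the seedlings changed together between the comparisons.

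Per the file headers, the deposited table gives 1 intensity per gene and dye under the name sVOL, for 14420 rows. The scanner, the image software and the background method are not given in the sources used here, nor is the meaning of that name. The highest intensity was 334 to 339 sVOL in every channel, and whether this was an upper limit of the measurement is not known here. Ratios of the brightest genes would be compressed if it was. These intensities never went below 0, and between 619 and 2368 genes per channel were listed at exactly 0. In all, 4977 genes (34.5%) were at 0 in at least 1 of the channels. Per the file headers, the authors added 0.00001 to every intensity, took the log2 ratio of test over reference and then subtracted each array's median. The deposited log2 values of the series matrix were the same centred ratios. With so small a constant, a 0 in 1 channel gives a very large log2 ratio, so these ratios were used as an alternative and not as the main values.

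The intensities were reprocessed in R 4.3.3 with limma 3.58.1. Each channel was scaled to a common median of 1.55 sVOL, an offset of 0.773 sVOL was added, log2 ratios were taken, and each array was normalised by loess on intensity (span 0.3, 4 iterations) with no step between arrays. A log2 fold change is therefore on the log2(value + offset) scale, which understates changes of dim genes. The design fixed before the data were examined did not say how values of 0 were to be handled, so the offset was added afterwards. Offsets of 0.1, 0.25, 0.5, 1 and 2 times the common median were tried, and 0.5 was kept because the residual spread was flattest over 5 intensity bins (highest over lowest median 1.28, against 1.38 for the whole median and 1.69 for 0.25). The numbers of genes called under all 5 offsets had already been seen when that rule was adopted, so the choice was not blind to them. The closing section gives the counts under the others.

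All 4 arrays entered 1 limma fit with a coefficient per comparison (2 residual degrees of freedom, moderated with 7.62 prior degrees of freedom). Tests were 2-sided against 0, with Benjamini-Hochberg adjustment over the 14420 rows at 0.05. The mean of the coefficients and their difference (stm day 10 minus Ler day 5) were tested in the same fit. Errors given with log2 fold changes are the moderated standard errors, with n = 2 arrays per comparison. A count of genes at least 2-fold changed the same way on both arrays was made without an error model.

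Gene names came from the table and from the TAIR10.1 annotation table, in which 14270 rows found their locus code and 7363 a symbol. No coordinates are given, since the files name no build. Before the data were examined, 26 gene lists with 321 members were fixed, of which 253 members were measured. Members counted in the results are the measured ones, such as 6 of 14 in the jasmonate list and 7 of 14 in the organ boundary list. Not measured were, among others, VSP1, VSP2, PDF1.2 and JAZ1 of the jasmonate list and LAS of the organ boundary list. No row carried the code of a member of the LSH family list, which left 25 lists for testing. A row with a code close to that of LSH4 is described with the results. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Each had Benjamini-Hochberg adjustment over the 25 lists. The test with an estimated correlation rests on the 2 residual degrees of freedom, so with 4 arrays it could hardly call a list. For the salicylate list in stm, camera p rose from 0.00117 to 0.0777 although the correlation was estimated at −0.125. A failure there leaves a list undecided and does not show that correlation between members made the call. The brightest row stood for a gene with several rows. Genes named in the text are, first, the fixed boundary and meristem genes and up to 4 members per list. To these are added the 10 highest and 10 lowest genes per comparison that passed the threshold and had the same sign on both arrays. Where fewer passed, the places were filled with the genes of smallest p that were at least 2-fold the same way. The 5 highest and lowest of the mean and difference complete the rule. Any gene outside this rule is said to be so.

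The procedure was tested on simulated data built from the measured intensities and spread, with 200 of 14420 genes changed in each comparison. For the Ler comparison 4% of genes changed 2-fold were recovered, 56% of those changed 4-fold, 98% of those changed 8-fold and 100% of those changed 16-fold. For the stm comparison the shares were 4%, 54%, 100% and 100%. Unchanged genes made up 4 of 133 calls and 8 of 137 calls. The simulated noise was independent between genes, so the simulation says nothing about correlated genes. Each gene also had the same simulated spread in both comparisons, and no dye bias of its own. The share of false calls therefore does not carry over to measured data in which either differs. The simulated fits held 133 and 137 calls, against 10 and 12 in the measured data, which makes the adjusted threshold looser. At the median standard error, a log2 fold change of 3.15 is needed to pass when there is 1 call. The recovered shares therefore overstate what the fit of the measured data could recover. The number of arrays limits the precision of every value.

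The alternatives covered a floor without an offset, median centring, scale normalization, a filter on dim genes, terms for dye and replicate number, separate fits, other moderation, the authors' ratios, another threshold, other fold limits and each array left out in turn. Other offsets, treating 0 as missing, keeping only genes above 0 in every channel, a crossed pairing, and leaving CUC1 out of the organ boundary list were added after the data had been examined. Probe sequences were not used here, so signal shared between related genes was not examined.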

Results

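CUC1 is a NAC-domain transcription factor that acts in the boundaries between organs and in the formation of the shoot meristem, and STM is a KNOX homeodomain protein that maintains that meristem. Transcripts were measured in cotyledons of seedlings that overexpressed CUC1 from the 35S promoter, against their controls, in wild-type Ler at day 5 and in the stm mutant at day 10. Each comparison had 2 arrays with swapped dyes. The median deposited intensity of a channel lay between 0.744 and 3.46 sVOL, and the highest between 334 and 339 sVOL. Between 619 and 2368 of the 14420 genes in a channel were listed at 0.

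CUC1 itself (AT3G15170) was higher in 35S:CUC1 on all 4 arrays. Its intensity was 1.05 in Ler and 6.40 in 35S:CUC1 on replicate 1, and 0 and 11.8 on replicate 2. In the stm background it was 0.177 and 10.4 on replicate 1, and 0 and 5.55 on replicate 2. The log2 fold change of CUC1 was 3.67 ± 0.37 (SE, n = 2, limma adjusted p = 0.0271) in stm. In Ler it was 2.48 ± 0.37 (SE, n = 2, limma adjusted p = 0.059) and did not pass the threshold, which it passed without either stm array (adjusted p = 0.000193 for each). Without Ler replicate 1 the value was 2.99 (adjusted p = 0.465), and without Ler replicate 2 it was 1.98 (adjusted p = 0.9998). In stm CUC1 passed without any 1 of the arrays, but not with scale normalization (3.39, adjusted p = 0.0645), an offset of 0.25 or 0.1 times the common median (4.45 and 5.38, adjusted p = 0.320 and 0.639), the floor (5.76, adjusted p = 0.677), 0 as missing (6.05, adjusted p = 0.371) or the authors' ratios (12.46, adjusted p = 0.772). The log2 difference between the comparisons was 1.18 (SE 0.52, adjusted p = 0.786). Where a control was listed at 0, the fold change depended on the offset.

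**Figure D1:**
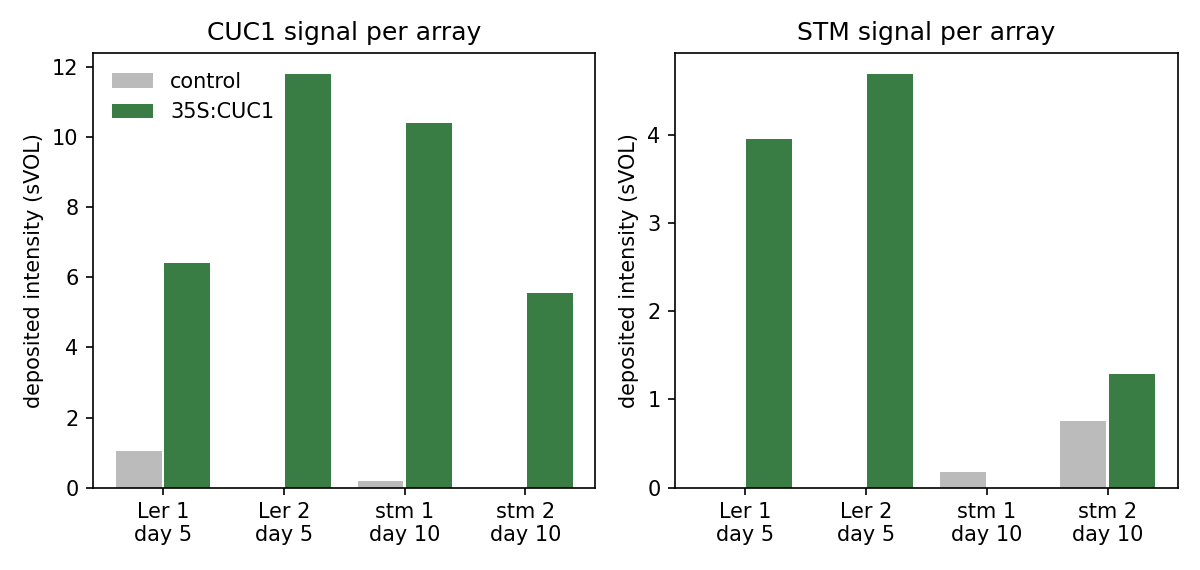
Deposited intensity (sVOL, vertical axis) of CUC1 and STM on each of the 4 arrays (horizontal axis), with grey bars for the control and green bars for 35S:CUC1. CUC1 reached 5.55 to 11.8 in 35S:CUC1 on every array, and STM reached 3.95 and 4.69 in 35S:CUC1 at day 5, where both Ler controls were at 0.

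The first comparison asked which transcripts differ in Ler cotyledons when CUC1 is overexpressed, at day 5. Of the 14420 genes tested, the largest increase was that of the peroxidase gene AT5G58390, with a log2 fold change of 4.59 ± 0.32 (SE, n = 2, adjusted p = 0.00118). A second peroxidase gene, AT4G37520, rose by 3.07 ± 0.31, the receptor kinase gene AT4G27300 by 3.14 ± 0.35 and AT5G61290 by 2.94 ± 0.33. BLH9 (AT5G02030), a BELL-type homeodomain protein that partners KNOX proteins, rose by 2.85 ± 0.32 (adjusted p = 0.0149 for each of these 4 genes). The small heat shock protein gene HSP17.6A (AT5G12030) fell by 2.81 (SE 0.36), the wax synthesis gene CER1 (AT1G02205) by 2.80 (SE 0.34), the cold-regulated gene COR15B (AT2G42530) by 2.73 (SE 0.34) and IMS2 (AT5G23020), of glucosinolate synthesis, by 2.52 (SE 0.32), with adjusted p from 0.0243 to 0.0244.

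In this comparison 10 of 14420 genes passed, 6 higher and 4 lower. The remaining gene of the 10 was AT3G23295 (log2 fold change 3.36 ± 0.37, adjusted p = 0.0149), whose code is absent from the annotation table and which is named here after its values were seen. That code is close to the code of LSH4 (AT3G23290), and whether the probe measures LSH4 is not known here. STM (AT1G62360) was listed at 0 in both Ler channels and at 3.95 and 4.69 in the 35S:CUC1 channels, so no fold is given, and it did not pass (limma adjusted p = 0.059). SEN1 (2.14 ± 0.31) and AT5G42500 (2.19 ± 0.32) had the same adjusted p. AT4G37220 stood at 2.01 (adjusted p = 0.0727). Among lower values that did not pass were COR15A at −2.18 (adjusted p = 0.059), BGLU18 at −2.03 (0.0698), HSP17.6II at −2.06 and AT5G48570 at −1.99 (0.0727 for both), MBF1C at −1.89 (0.078) and HPL1 at −1.98 (0.104).

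Of the other boundary and meristem genes fixed beforehand, CUC2 had a log2 value of 0.44 ± 0.36, CUC3 0.48 ± 0.32, KNAT1 0.36 ± 0.31, KNAT2 −0.047 ± 0.36 and KNAT6 0.87 ± 0.31. The leaf genes AS1 and AS2 stood at 0.51 ± 0.33 and −0.33 ± 0.32. None of these 7 passed in Ler.

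At day 5, 7 of the 25 gene lists passed with camera at the preset correlation, and 0 passed with an estimated correlation or with fry, where 0 and 5 lists had an unadjusted p under 0.05. Of the 15 shoot meristem and KNOX genes 1 rose, BLH9, 0 fell and 9 had values above 0 (median 0.36, camera adjusted p = 0.000566, adjusted p = 0.429 with an estimated correlation). The median was 0.11 on Ler replicate 1 and 0.38 on Ler replicate 2. Members of this list were listed at 0 in a median of 2 channels over all arrays, the most of the 25 lists. Much of its shift can therefore rest on the offset. Adjusted over the list alone, 2 passed. Of the 7 organ boundary genes 0 passed and 6 had values above 0 (median 0.44, adjusted p = 0.00705, adjusted p = 0.429 with an estimated correlation). This list holds CUC1, the overexpressed gene, and without it the other 6 did not pass (median 0.41, adjusted p = 0.228). The leaf senescence list, with 0 of 7 passing, had a median of 0.36 (adjusted p = 0.0189, adjusted p = 0.429 with an estimated correlation), which was −0.053 on Ler replicate 1 and 0.16 on Ler replicate 2 alone.

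The other 4 lists lay lower in 35S:CUC1 at day 5. Of the 7 cold and abscisic acid response genes 1 fell, COR15B, and 5 had values below 0 (median −0.68, adjusted p = 0.000154, adjusted p = 0.429 with an estimated correlation). COR15A and RAB18 in this list had values of −2.18 and −1.37, and 3 members passed adjusted over the list alone. The list's median was −1.71 on Ler replicate 1 and 0.38 on Ler replicate 2, so the arrays differed in direction. The heat shock list had 0 of 7 members passing and 6 below 0 (median −0.54, adjusted p = 0.000566, adjusted p = 0.548 with an estimated correlation), with HSP101 at −1.50 and HSP70-4 at −1.26, and its median was −0.95 on Ler replicate 1 and −0.45 on Ler replicate 2. The jasmonate list had 0 of 6 members passing (median −0.82, adjusted p = 0.000566, adjusted p = 0.429 with an estimated correlation). Its lowest values were those of the jasmonate synthesis genes LOX2 (−1.17) and AOS (−1.01). The anthocyanin and flavonoid list had 0 of 14 passing (median −0.31, adjusted p = 0.0189, adjusted p = 0.429 with an estimated correlation), with PAP1 at −1.22 and DFR at −0.96.

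Without Ler replicate 1 only 2 lists passed at day 5, the meristem and the jasmonate list, and without Ler replicate 2 there were 4. By size alone, 77 genes were at least 2-fold higher and 32 at least 2-fold lower on both Ler arrays, against 31 that were 2-fold changed in opposite directions. At an unadjusted p under 0.05 there were 587 genes, where 721 would be found by chance. In limma there were 808 in a fit of the Ler arrays alone, 825 with scale normalization and 523 with median centring. Whether the Ler count lay above that found by chance thus depended on the processing. The count of 10 became 0 without Ler replicate 1 (486 genes at an unadjusted p under 0.05 in limma), 1 without Ler replicate 2 and 67 without either stm array. It was 14 with an offset of the whole common median, 1 with 0.25 times that median, and 0 with 0.1 times that median, with a floor in place of the offset or with the authors' ratios, where limma had 544, 591 and 344 genes at an unadjusted p under 0.05.

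**Figure D2:**
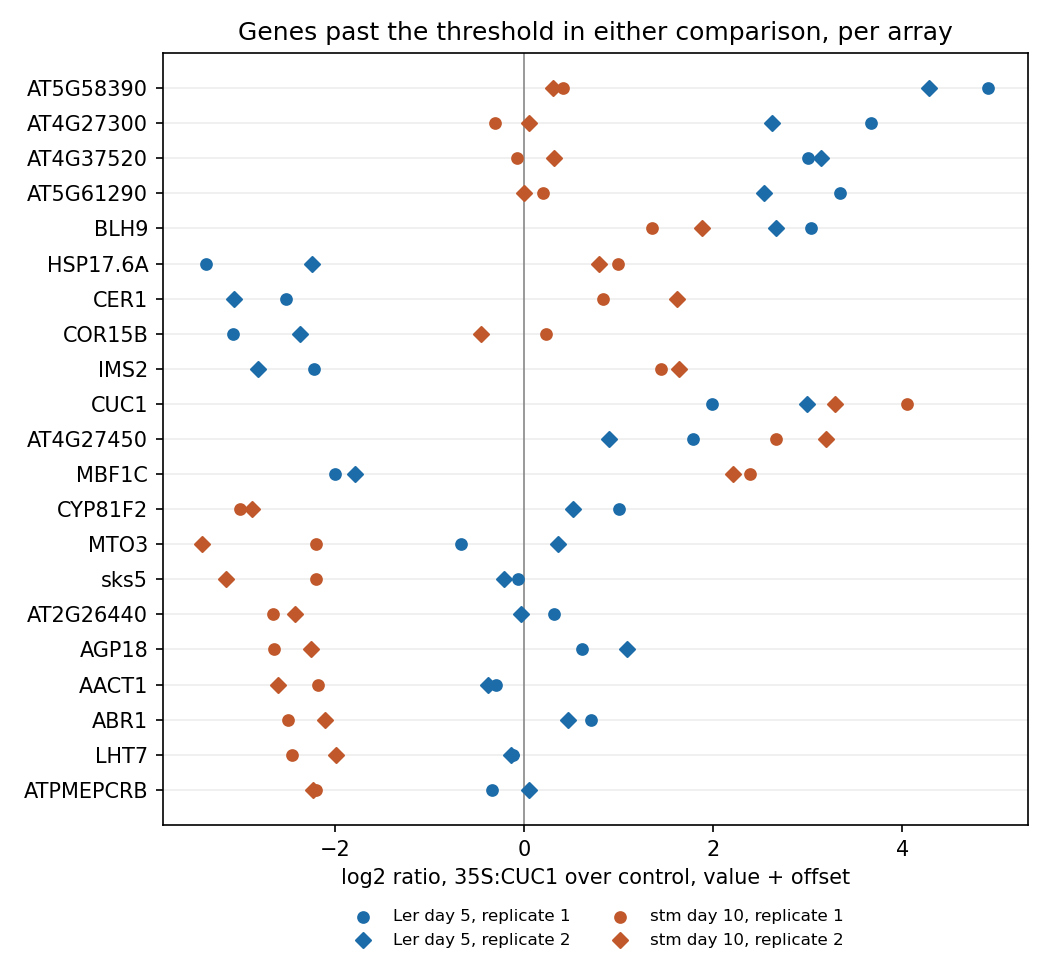
Log2 ratio of 35S:CUC1 over control (horizontal axis, value + offset scale) on each array for the named genes that passed the threshold in Ler (blue, day 5) or in stm (orange, day 10), with circles for replicate 1, diamonds for replicate 2, and AT3G23295 not drawn. AT5G58390 stood at 4.91 and 4.28 in Ler and at 0.41 and 0.30 in stm.

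The second comparison asked the same question in the stm mutant at day 10. Besides CUC1, AT4G27450, which the file names only as a putative protein, rose by 2.93 ± 0.35 (SE, n = 2, adjusted p = 0.0434) and the transcriptional coactivator MBF1C (AT3G24500), which acts in the heat response, by 2.30 ± 0.31 (adjusted p = 0.0466). CYP81F2 (AT5G57220), a cytochrome P450 of indole glucosinolate metabolism, fell by 2.95 (SE 0.31, adjusted p = 0.0271). MTO3 (AT3G17390), an S-adenosylmethionine synthetase, fell by 2.81 (SE 0.40, adjusted p = 0.049), and the arabinogalactan protein gene AGP18 (AT4G37450) fell by 2.45 (SE 0.32, adjusted p = 0.0434). The genes sks5 (AT1G76160), AT2G26440 and ATPMEPCRB (AT4G02330) fell by 2.68 (SE 0.34), 2.54 (SE 0.31) and 2.22 (SE 0.31), and the file names the first pair as pectinesterases.

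In stm 12 of 14420 genes passed, 3 higher and 9 lower. In a fit of the stm arrays alone 1 of these 12 was called, so the other calls rest on the spread shared with the Ler arrays. AACT1 (AT5G61160) fell by 2.39 (SE 0.31, adjusted p = 0.0434), the transcription factor gene ABR1 (AT5G64750) by 2.31 (SE 0.31, adjusted p = 0.0466) and the amino acid transporter gene LHT7 (AT4G35180) by 2.22 (SE 0.31, adjusted p = 0.049). Values that did not pass included those of AOP3 (2.11, adjusted p = 0.0531) and SOT18 (2.03, adjusted p = 0.0566), both of glucosinolate synthesis. They also included NCED4 at 2.18 and AT1G80440 at 2.14 (adjusted p = 0.0555 for both), AT1G34060 at 2.30 and COL5 at 1.97 (0.0619 for both), AT5G48570 at 1.95 (0.063) and AT5G10760 at −2.13 (0.0555). STM had a log2 value of 0.059 ± 0.32 (adjusted p = 0.982). With median centring the STM value was −0.12, and with the authors' ratios, where a 0 gives a very large ratio, it was −6.68. The value thus depended on the processing and does not show that STM was unchanged in stm. KNAT2 and KNAT6, given next, were likewise at −6.78 and −5.95 with the authors' ratios. CUC2 stood at 0.32 ± 0.36, CUC3 at 0.71 ± 0.32, KNAT1 at −0.34 ± 0.31, KNAT2 at 0.17 ± 0.36, KNAT6 at 0.16 ± 0.31, AS1 at 0.92 ± 0.33 and AS2 at −0.14 ± 0.32, and none of these passed.

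In stm 5 of the 25 lists passed with camera at the preset correlation, and 0 with an estimated correlation or with fry, where 0 and 5 lists had an unadjusted p under 0.05. When stm replicate 1 was left out, 0 lists passed with camera. Of the 7 organ boundary genes 1 rose, CUC1 itself, and 6 had values above 0 (median 0.32, adjusted p = 0.0244, adjusted p = 0.705 with an estimated correlation). Without CUC1 the other 6 did not pass (median 0.28, adjusted p = 0.512). The heat shock list had 0 of 7 members passing and 6 above 0 (median 0.62, adjusted p = 0.00297, adjusted p = 0.796 with an estimated correlation), with HSP70-4 at 2.02 and HSP90.1 at 1.69. Adjusted over the list alone, 3 of these 7 passed.

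The remaining 3 lists were lower in 35S:CUC1 stm. All 9 salicylate and pathogen response genes had values below 0 and 0 passed (median −0.45, adjusted p = 0.00973, adjusted p = 0.705 with an estimated correlation), with the pathogenesis-related gene PR2 at −1.91, and the median was −0.27 on stm replicate 1 and −0.39 on stm replicate 2. All 6 measured jasmonate genes, of 14 fixed, had values below 0 and 0 passed (median −0.69, adjusted p = 0.00466, adjusted p = 0.705 with an estimated correlation), with LOX2 at −1.51 and OPR3 at −1.08. Of the 10 type-A response regulators, which cytokinin induces, 0 passed and 8 were below 0 (median −0.47, adjusted p = 0.046, adjusted p = 0.705 with an estimated correlation), with ARR15 at −0.98 and ARR16 at −0.88. The median was −0.64 on stm replicate 1 and −0.067 on stm replicate 2. The type-A list did not pass once CUC1 was left out of the organ boundary list, which changed the adjustment over the lists (adjusted p = 0.0575).

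Marker lists for tissues that a cotyledon sample could carry did not pass in either comparison. Camera adjusted p at day 5 and in stm was 0.753 and 0.712 for trichomes, 0.753 and 0.628 for the stomatal lineage, 0.866 and 0.712 for vascular tissue, 0.777 and 0.628 for seed storage proteins, and 0.755 and 0.691 for the root epidermis. The lists for leaf polarity (0.228 and 0.628), the cell cycle (0.221 and 0.346), photosynthesis (0.804 and 0.712, with members near the highest intensities), CIN-type TCP genes (0.678 and 0.783), cytokinin metabolism (0.866 and 0.896), gibberellin metabolism (0.678 and 0.912), auxin response (0.678 and 0.712), auxin transport (0.678 and 0.628), the cuticle (0.755 and 0.628), flowering (0.755 and 0.712) and expansins (0.755 and 0.691) did not pass either.

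By size alone, 132 genes were at least 2-fold higher and 154 at least 2-fold lower on both stm arrays, against 123 changed 2-fold in opposite directions. At an unadjusted p under 0.05 there were 1424 genes, where 721 would be found by chance. In a limma fit of the stm arrays alone there were 1160. The count of 12 became 1 without either Ler array, 55 without stm replicate 1 and 58 without stm replicate 2. It was 78 with an offset of the whole common median, 3 with median centring, and 0 with scale normalization or with an offset of 0.25 times the common median, where limma had 1075 and 1308 genes at an unadjusted p under 0.05.

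Over both comparisons together, CUC1 had a mean log2 fold change of 3.08 ± 0.26 (SE, 4 arrays, adjusted p = 0.00652). BLH9 rose by 2.23 ± 0.23 (adjusted p = 0.0119), AT4G27450 by 2.13 ± 0.25 (adjusted p = 0.026) and SEN1 by 1.77 ± 0.22 (adjusted p = 0.0299), each higher on 4 of 4 arrays. AT5G58390 had a mean of 2.47 ± 0.23 (adjusted p = 0.00707), from 4.59 in Ler and 0.35 in stm. The beta-glucosidase gene BGLU18 fell by 1.80 (SE 0.22, adjusted p = 0.0299) and the hydroperoxide lyase gene HPL1 by 1.78 (SE 0.24, adjusted p = 0.0425), each lower on 4 of 4 arrays, and the beta-amylase gene BAM5 stood at −1.32 (adjusted p = 0.0742). In all 10 genes passed, 8 higher and 2 lower, and 11 genes were at least 2-fold higher and 3 at least 2-fold lower on all 4 arrays. The count of 10 was 1 and 0 without Ler replicate 1 or 2, where the latter left 790 genes at an unadjusted p under 0.05 in limma, and 100 and 53 without stm replicate 1 or 2. CUC1 did not pass for the mean without Ler replicate 2 (adjusted p = 0.0668).

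For the mean of both comparisons 5 lists passed with camera at the preset correlation, and 0 with an estimated correlation (0 lists at an unadjusted p under 0.05). The jasmonate list had a median of −0.86 (adjusted p = 0.000137, adjusted p = 0.545 with an estimated correlation) and the organ boundary list 0.38 (adjusted p = 0.00312, adjusted p = 0.545 with an estimated correlation). The cold and abscisic acid list stood at −0.36 (adjusted p = 0.0120, adjusted p = 0.545 with an estimated correlation), but its arrays differed in direction, with medians of −1.71 and 0.38 on Ler replicates 1 and 2 and 0.23 and −0.21 on stm replicates 1 and 2. The salicylate list stood at −0.24 (adjusted p = 0.0429) and the meristem list at 0.061 (adjusted p = 0.0443), with adjusted p = 0.545 with an estimated correlation for each. Only the organ boundary list passed with fry (adjusted p = 0.0357), and without CUC1 it passed neither with fry (adjusted p = 0.162) nor with camera (adjusted p = 0.106). The salicylate and meristem lists then also did not pass with camera (adjusted p = 0.0554 for both).

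The effects of the overexpression differed between the comparisons for 7 genes, 5 higher and 2 lower in stm at day 10 than in Ler at day 5. MBF1C had a log2 difference of 4.19 ± 0.43, IMS2 of 4.06 ± 0.45 and AT5G48570 of 3.94 ± 0.44 (adjusted p = 0.0199 for each). CER1 differed by 4.02 ± 0.48 (adjusted p = 0.0248) and the mitochondrial heat shock gene AT5G51440 by 3.91 ± 0.48 (adjusted p = 0.028). The difference was −4.24 ± 0.45 for AT5G58390 (adjusted p = 0.0199) and −3.71 ± 0.44 for CYP81F2 (adjusted p = 0.0248). It was −3.30 for AGP18 (adjusted p = 0.051), −3.24 for AT4G21870 and −3.18 for scpl35 (0.0711 for both), which did not pass. STM did not pass for the difference (adjusted p = 0.264).

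Among the lists, heat shock (median difference 0.996, adjusted p = 6.98e-06, adjusted p = 0.697 with an estimated correlation) and the cold and abscisic acid response (median difference 0.81, adjusted p = 0.00881, adjusted p = 0.697 with an estimated correlation) passed for the difference. The median difference of the cold and abscisic acid list was −0.29 without Ler replicate 1 (adjusted p = 0.518) and 0.39 without stm replicate 1 (adjusted p = 0.180), against 1.77 without Ler replicate 2 and 1.24 without stm replicate 2, while heat shock passed without any 1 of the arrays. With fry only the auxin transport list passed for the difference (adjusted p = 0.0487), with all 8 values below 0, a median of −0.27 and 0 members passing. With camera it did not pass (adjusted p = 0.348, adjusted p = 0.816 with an estimated correlation). Background and age cannot be told apart in these values. The count of 7 was 0 without either Ler array (748 and 478 genes at an unadjusted p under 0.05 in limma), 46 without stm replicate 1 and 53 without stm replicate 2.

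In limma 0 genes passed in both comparisons, and 71 had an unadjusted p under 0.05 in both with the same direction, against 55 with opposite directions. By direction, independent lists of these sizes would share 0.00125 genes higher and 0.00250 lower. Across genes, which are not independent replicates, the log2 fold changes of Ler and stm had a Pearson correlation of 0.0668 and a Spearman correlation of 0.0645. Ratios of the Ler arrays correlated with each other at 0.0478 across genes and those of the stm arrays at 0.145, while arrays of the same dye orientation correlated across comparisons at 0.206 and 0.0836.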

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

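The tests of dye and of single arrays for heat shock, the meristem list test and the dye correlation were chosen after the results they bear on had been seen; the test on other heat shock genes and that on the STM signal were set before.

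A test of the difference between the comparisons picked out 7 genes. The log2 differences, stm day 10 minus Ler day 5, were 4.19 for MBF1C, 4.06 for IMS2, 4.02 for CER1, 3.94 for AT5G48570, 3.91 for AT5G51440, −3.71 for CYP81F2 and −4.24 for AT5G58390. The same test on lists, with camera at the preset correlation, picked out heat shock (median difference 0.996) and the cold and abscisic acid response (median difference 0.81), and neither passed with an estimated correlation (adjusted p = 0.697 for both). The latter rested on Ler replicate 1: without it the median difference was −0.29 (adjusted p = 0.518), and without stm replicate 1 it was 0.39 (adjusted p = 0.180), against 1.77 without Ler replicate 2 and 1.24 without stm replicate 2.

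The heat shock list had a median below 0 in Ler and above 0 in stm, with 0 of 7 members passing in either comparison, and with an estimated correlation it did not pass (adjusted p = 0.548 in Ler, 0.796 in stm and 0.697 for the difference). A dye bias shared by the arrays would give opposite signs on swapped arrays. The list's median was −0.95 and −0.45 on the Ler arrays and 0.72 and 0.52 on the stm arrays. The value nearest to 0, −0.45 on Ler replicate 2, lay beyond its standard error of 0.21 over the 7 members. That error treats the members as independent, although their correlation was estimated at 0.376, and 3 of the 7 were above 0 on that array. The signs of the medians go against such a dye bias but do not exclude it. No single array carried the difference between the comparisons, for which the highest adjusted p without one array was 0.00661 (camera, preset correlation). Within a comparison the list did depend on single arrays: it no longer passed in Ler without Ler replicate 1, or in stm without stm replicate 1. A heat-stress state that differed between the sampled plants remains a candidate explanation: 64 further genes named as heat shock proteins, outside the list and the named genes, also had higher effects in stm (46 of 64, median difference 0.31, camera p = 1.27e-06, p = 0.0252 with an estimated correlation, both unadjusted). The full family of 75 such genes did not pass for the difference with an estimated correlation and adjustment over all 75 family tests (adjusted p = 0.465). Whether such a state would come from genotype, age or handling was not tested, and the design does not separate them.

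STM was listed at 0 in both Ler channels and above 0 in both 35S:CUC1 channels at day 5. Chance signal of a dim gene is argued against, since 0 of 294 other genes at 0 in both Ler channels reached STM's scaled signals on both arrays (0%, exact 95% interval up to 1.25%). Whether meristem genes as a whole were higher stays open: without STM and BLH9 the list had 7 of 13 values above 0 (median 0.02, SE 0.15, camera p = 0.0593, p = 0.184 with an estimated correlation). Signal from related KNOX transcripts was not tested.

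Arrays of the same dye orientation resembled each other across the comparisons, with a mean correlation of 0.145 against −0.07 for opposite orientations (difference 0.213). A gene-specific dye bias may account for it, but a pairing of Ler replicate 1 with stm replicate 2 makes the same prediction, and these cannot be told apart because the dye and that pairing are the same term.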

How the results depend on the processing

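Settings named in the plan came first; the other offsets, 0 as missing, genes above 0 in every channel, the crossed pairing and lists without CUC1 were chosen after the data had been seen. Counts of genes are given in the order Ler, stm, mean, difference, and stood at 10, 12, 10 and 7 in the analysis as reported. They depended strongly on the processing. The part played by the spread shared between the comparisons is given with the separate fits. Other causes were not tested unless fewer genes or arrays are named.

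Counts were 0, 0, 0 and 0 with a floor in place of the offset (591, 977, 849 and 658 genes at an unadjusted p under 0.05 in limma), 9, 3, 8 and 5 with median centring, 27, 0, 13 and 9 with scale normalization (1075 at an unadjusted p under 0.05 for stm), 23, 34, 42 and 16 without dim genes, 29, 57, 49 and 18 with a dye term, 32, 64, 53 and 17 with trend and robust moderation, 0, 86, 0 and 0 with the authors' ratios (344, 641 and 517 at an unadjusted p under 0.05 where 0 passed) and 23, 57, 52 and 16 at a threshold of 0.10. Separate fits gave 67 in Ler and 1 in stm. All 10 genes called in Ler were called in its own fit, but only 1 of the 12 called in stm. The other stm calls thus rest on the spread shared with the Ler arrays. A separate fit also has fewer residual degrees of freedom. Across genes, the ratios varied more on the stm arrays (SD 0.612 and 0.666) than on the Ler arrays (0.511 and 0.537). That SD mixes effects with noise and is not the spread between replicates. Leaving out an array of 1 comparison repeats the separate fit of the other comparison. With an offset of 0.1 times the common median they were 0, 0, 0 and 0 (544, 1068, 850 and 711 at an unadjusted p under 0.05), with 0.25 times 1, 0, 2 and 0 (1308 and 826 where 0 passed), with the whole 14, 78, 39 and 14, and with 2 common medians 4, 93, 22 and 2. Treating 0 as missing gave 0, 0, 0 and 0 (800, 1445, 1125 and 978), and genes above 0 in every channel gave 27, 55, 50 and 16.

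Of the genes called, all 10, 12, 10 and 7 were called again with the dye term, without dim genes, with trend and robust moderation and with the whole common median. With the floor and with the authors' ratios 0 were. With median centring 9, 3, 8 and 5 were, and with scale normalization 10, 0, 10 and 7.

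The replicate numbers were not shown to pair the arrays: the deviations of same-numbered arrays correlated at −0.241 across genes. With a replicate block the counts were 49, 106, 76 and 44, and 4 genes were called the same way in both comparisons. The crossed pairing, chosen after that check, is the same term as the dye and gave 29, 57, 49 and 18.

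With single arrays left out (Ler replicate 1, Ler replicate 2, stm replicate 1, stm replicate 2: Ler 0, 1, 67, 67; stm 1, 1, 55, 58; mean 1, 0, 100, 53; difference 0, 0, 46, 53), where the lone array of a comparison is assumed to vary like the others, the counts ranged from 0 to 67 in Ler, 1 to 58 in stm, 0 to 100 for the mean and 0 to 53 for the difference. Genes called in both ranged from 0 to 1, the CUC1 value in Ler from 1.98 to 2.99, and lists called from 2 to 7 in Ler, 0 to 5 in stm and 1 to 5 for the difference. Signs changed for genes that did not pass: CUC2 in Ler ranged from −0.061 (without Ler replicate 1) to 0.94, KNAT2 in Ler from −0.20 to 0.10 (without Ler replicate 1), AS2 in stm from −0.34 to 0.074 (without stm replicate 1), and STM from −0.17 to 0.29, KNAT2 from −0.42 to 0.75 and KNAT6 from −0.069 to 0.39 in stm (lowest without stm replicate 2). Medians of lists that passed also changed sign: cold and abscisic acid in Ler ranged from −1.71 to 0.38 and its difference from −0.29 to 1.77 (0.38 and −0.29 without Ler replicate 1), and leaf senescence in Ler from −0.053 (without Ler replicate 2) to 0.36.

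CUC1 in Ler (2.48) passed with scale normalization (2.71, adjusted p = 0.0311), and at 2.48 without dim genes, with the dye term, the replicate block, a separate fit, trend and robust moderation and the threshold of 0.10 (adjusted p from 1.22e-05 to 0.059). CUC1 in stm no longer passed with the floor (5.76), scale normalization (3.39), the authors' ratios (12.46), an offset of 0.1 times (5.38) or 0.25 times (4.45) the median, or 0 as missing (6.05), with adjusted p from 0.0645 to 0.772. None of these genes passed when reversed: with median centring STM in stm was −0.12 and KNAT2 −0.080, with the authors' ratios STM was −6.68, KNAT2 −6.78 and KNAT6 −5.95 in stm, and with 0 as missing KNAT2 in Ler was 0.18.

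The number of genes called the same way in both comparisons was 1 without dim genes, 1 with the dye term, 2 with trend and robust moderation, 1 at the threshold of 0.10 and 2 with the whole common median. The correlation of the comparisons across genes ranged from −0.03 to 0.132 over all settings. Genes at least 2-fold changed the same way in Ler and stm, 109 and 286 as reported, were 495 and 728 with the floor, 929 and 1471 with the authors' ratios, 425 and 699 with 0.1 times, 184 and 466 with 0.25 times, 175 in stm with the whole, 46 and 126 with 2 common medians, and 481 and 656 with 0 as missing. At 1.5-fold they were 531 and 1099, against 478 and 685 changed in opposite directions. At 3-fold they were 31 and 43, against 1 and 13.

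Lists called with camera, 7 in Ler, 5 in stm and 2 for the difference as reported, were 0, 0 and 0 with an estimated correlation. With the authors' ratios they were 2 in Ler and 3 in stm, with 0 as missing 4 and 2, and with 2 common medians 3 in stm. Without CUC1 in the organ boundary list they were 6 in Ler, 3 in stm and 2 for the difference. For the difference they were 1 with the floor, 4 with median centring, 6 at the threshold of 0.10, 4 with 0.1 times, 5 with 0.25 times and 4 with genes above 0 in every channel. Values under other settings were given only for lists that passed as reported, and other lists enter only the counts. Signal near 0 limits part of the table: 34.5% of genes were at 0 in at least 1 channel, where the ratio rests on the offset by construction.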

Other observations

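The families below were chosen after the data had been seen. Of the tests reported here, those on the remaining glucosinolate and pectinesterase genes were set before their results were seen. With so few arrays, a failure of a family with an estimated correlation leaves it undecided, as for the lists.

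Genes of glucosinolate synthesis, defence compounds of the cabbage family, had mostly higher values in 35S:CUC1 stm, but 0 of 21 passed singly and the family did not pass with an estimated correlation (adjusted p = 0.465 over all 75 family tests). In stm 19 of 21 values were above 0 (median log2 1.15, and 1.34 and 1.15 on the single arrays). CYP81F2, of indole glucosinolate metabolism, passed as lower in stm but is not in this family, so the values cover only the 21 listed genes. MAM1, named with the next genes after the values were seen, stood at 1.83, SOT17 at 1.85, FMO GS-OX1 at 1.85 and BCAT4 at 1.57. The median was 1.29 with median centring, 1.08 with scale normalization and 1.37 in the authors' ratios. In Ler the family's median was 0.36 (0.29 and 0.16 on the single arrays), with 11 of 21 values above 0. The only member that passed in Ler, IMS2, was lower. The regulators MYB28 and MYB29 stood at 2.02 and 2.49 there but did not pass (limma adjusted p = 0.104 and 0.078). The hypothesis that the listed genes as a whole changed in stm was tested without IMS2, AOP3 and SOT18, which had prompted it. Of the other 18 genes 16 were higher (median 1.05, SE 0.15, camera p = 6.63e-13, p = 0.0161 with an estimated correlation).

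Genes for cytosolic ribosomal proteins had mostly lower values in stm, but 0 of 102 passed singly and the family did not pass with an estimated correlation (adjusted p = 0.730). In stm 93 of 102 values were below 0 (median −0.53, and −0.32 and −0.61 on the single arrays). In Ler 83 of 102 were below 0 (median −0.15, adjusted p = 0.0212 at the preset correlation and 0.730 with an estimated one), but the median was −0.27 on Ler replicate 1 and 0.00089 on Ler replicate 2, so the shift in Ler was absent on 1 of its arrays. The median in stm was −0.39 with median centring, −0.45 with scale normalization and −0.48 in the authors' ratios. In the same order it was −0.062, −0.31 and −0.14 on stm replicate 1, and −0.60, −0.52 and −0.69 on stm replicate 2. Of 26 histone genes 22 had values above 0 in Ler (median 0.19, and 0.060 and 0.27 on replicates 1 and 2) and 6 in stm (median −0.20, and −0.32 and −0.073 on replicates 1 and 2), with the same signs of the medians under median centring, scale normalization and the authors' ratios, but neither comparison passed at the preset correlation (adjusted p = 0.0586 in Ler and 0.234 in stm). The difference passed there (adjusted p = 0.0212) but not with an estimated correlation (adjusted p = 0.730).

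Because AT2G26440 and ATPMEPCRB fell in stm, pectinesterase genes were tested as a family without them. The family was taken from the file's gene descriptions and does not include ATPMEPCRB, so only AT2G26440 was removed, while sks5, which also fell, stayed in. The test was therefore not independent of the falls already seen. The other 66 genes had a median of −0.05 (SE 0.07), with 35 below 0 and 31 above. Both criteria set beforehand were met: camera gave p = 0.0332 in the direction of a fall (p = 0.112 with an estimated correlation), and the median lay within the bound of 0.2 set for no fall of the family as a whole. A fall of most members was thus not seen, and a fall of some members is not excluded.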
